A study of Mus musculus with 2 samples.

How the data were processed

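Single-nucleus RNA sequencing was analysed for the hippocampus of 3-month-old mice carrying a conditional deletion of Stra8 (genotype Stra8L/- with Nestin-Cre, per the labels; Nestin-Cre drives the recombinase in neural progenitors and so in the neurons and macroglia they give rise to). There were 2 libraries, 1 from the male and 1 from the female group, and no library of another genotype, so the comparison made was between the male and the female library. Nuclei were captured by droplet emulsion with 3' v3.1 chemistry at a target of 10000 nuclei per sample, per the labels' protocols. The deposited values are raw UMI counts per gene and barcode (a UMI is a molecular tag, so that copies of 1 molecule made by PCR are counted once), made with Cell Ranger 7.0.1 per the file headers. Reads were demultiplexed with bcl2fastq 2.20.0.422 and aligned to mm10, per the submitters' processing notes. The annotation release, the use of intronic reads and the rule by which barcodes were called as nuclei were not given in the sources used here. The lowest deposited barcode held 502 UMIs in the male and 500 in the female library. Both libraries list the same 32285 genes under 32245 symbols. Of these symbols, 32196 were matched by gene identifier to the GENCODE vM21 annotation of the mm10 build, from which positions were taken.

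The male library held 103262825 UMIs over 16174 barcodes, and the female library 108286856 UMIs over 20150 barcodes. Barcodes with at least 500 genes and at most 5% mitochondrial UMIs were used, which left 16034 male and 19251 female nuclei. Doublets were called per library with Scrublet in scanpy at an expected rate of 8%. Its automatic threshold called 9.57% of the male nuclei (1534 nuclei) and 0% of the female nuclei. Because a caller that marks under 0.5% has not worked, the female nuclei at the top 8% of scores were called instead, and the ties at that score left 7.51% called (1445 nuclei). The 2 libraries were therefore treated by different thresholds. Called nuclei were removed, and so were 5 of 33 clusters with over 40% called nuclei, which left 14007 male and 17224 female nuclei.

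Counts of both libraries were scaled to the same total per nucleus and log-transformed. The 3000 most variable genes within libraries were scaled and reduced to 40 principal components, and a graph of 15 neighbours was clustered by the Leiden method at resolution 1 without integration. Stra8, the sex-linked check genes and the mitochondrially encoded genes were left out of the clustering. Clusters were named from marker lists of 8 genes per type. A cluster took the class whose 4 best markers had the highest mean fold over all other nuclei, if at least 3 markers lay over 2-fold at 20 CPM or more and its 20 leading genes held more markers of that class than of another. A cluster of low UMI count also needed a marker among its 10 leading genes. A name means that the nuclei are like that type, and the suffix "-like" is left out for brevity. The marker lists, filters, resolution, ratio and rule for named genes were fixed before the data were examined; the scoring details of the naming were not, and the low-UMI step was rewritten after the data were seen, which left the names unchanged. Main classes were the 8 largest of the named classes with at least 200 nuclei in each library, which left out oligodendrocyte precursors (359 and 497 nuclei). All 15 of their 15 clusters had at least as many markers of their own class as of another among the 10 leading genes.

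CPM were computed here from the deposited counts. UMIs were summed per library and class, expressed as CPM of the class total, and ratios were log2 of male CPM plus 5 over female CPM plus 5, so ratios of low genes are understated. Intervals of UMI sums are exact Poisson, those of ratios exact conditional binomial, those of shares exact Clopper-Pearson, all at 95%; they cover counting error only. With 1 library per group no test was run and no p-value is given: sex, animal, dissection and library cannot be told apart. A gene or share at 0 was given the limit of 3 counts.

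Genes were named by a rule of size. Shared genes had at least 50 UMIs over both libraries and at least 20 CPM in either library in at least 4 main classes, with 1 sign throughout, and the 10 with the largest median ratio each way were taken. Class genes had at least 100 UMIs and 20 CPM and were the 3 highest and 3 lowest per main class outside the shared genes and the markers of other classes. The 28 gene lists were each tied to a focus class beforehand: meiotic entry and prophase, retinoic acid signalling, X-linked genes that escape inactivation, sex steroid receptors and synthesis, and adult neurogenesis (all nuclei); immediate early genes, synaptic vesicle release, voltage-gated sodium and calcium channels, potassium channels, circadian clock, heat shock and protein folding, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, cohesin and chromatin regulators, and DNA damage and apoptosis (dentate gyrus granule neurons); ionotropic glutamate receptors, GABA-A receptors, and calcium and plasticity kinases (CA1 neurons); neuropeptides and receptors (GABAergic interneurons); myelin, oligodendrocyte cholesterol and lipid synthesis, and glucocorticoid response (oligodendrocytes); homeostatic and reactive astrocyte genes (astrocytes); and homeostatic microglia, activated microglia and interferon response (microglia). Each list was given its median ratio over members with at least 50 UMIs, the percentile of that median among 10000 random lists of the same size matched on deciles of level, and its 2 highest and 2 lowest members. That percentile describes these libraries and is no test of sex.

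The ratios, intervals and random lists were tested on simulated data made from the real genes of the male to female comparison in the 8 main classes (8218 to 14562 genes, of which 200 were changed). The intervals covered the simulated ratio of 95.2% to 96.5% of genes, and of 93.5% to 96.5% of changed genes. The direction was recovered for 97.0% to 100% of genes changed 1.5-fold and for 100% of those changed 2-fold or 4-fold. Between 2% and 7% of unchanged lists fell outside the central 95% of random lists, and 100% of lists of 20 genes shifted 1.5-fold lay above it. All simulated counts were Poisson, and genes other than the 200 had equal levels in both libraries. These figures therefore check the computation and do not carry over to the wider spread of ratios in the real libraries.

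There were 12 alternatives fixed beforehand: all barcodes; at least 1000 genes and at most 1% mitochondrial UMIs; no doublet removal; Leiden resolution 0.5 and 2; gene values centred within each library before clustering; ratios centred on the median gene; the mean over nuclei of CPM; nuclei thinned to 1000 UMIs; a pseudocount of 1; and list members with at least 10 or at least 200 UMIs. The 3 added after seeing the data were removal of clusters with over 20% called doublets, shares over named classes only, and the stricter nucleus filter with the class names kept. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.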

Results

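Nuclear RNA of the hippocampus was profiled in 1 male and 1 female library from 3-month-old mice carrying a conditional deletion of Stra8 with Nestin-Cre. Stra8 (stimulated by retinoic acid 8) is known as the switch that commits germ cells to meiosis, and the labels state no further aim. The male library gave 16174 barcodes with a median of 4810 UMIs and 2433 genes, and the female library 20150 barcodes with a median of 2798 UMIs and 1638 genes. The median mitochondrial share was 0.614% and 1.47%. After filtering, 14007 male nuclei (median 4381 UMIs, 2285 genes) and 17224 female nuclei (median 2694 UMIs, 1590 genes) remained, from libraries aimed at 10000 nuclei each. With every nucleus thinned to 1000 UMIs, which left out 366 male and 1182 female nuclei, the medians were 731 and 714 genes. Each group has 1 library, so every comparison is between these libraries, and the intervals given are 95% intervals of counting error only.

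Stra8 (ENSMUSG00000029848; mm10 chromosome 6, 34920163 to 34939344) was close to undetected in both libraries. Over all barcodes it had 3 UMIs in the male library (Poisson interval 0.619 to 8.77) and 6 in the female library (2.2 to 13.1), each in a different barcode, and 2 and 4 of them lay in kept nuclei. The deleted exons are not given in the sources used here, so a 3' tag may lie outside the deleted part, and without a control genotype this level does not check the deletion. The sex-linked genes went with the labels. Xist, the RNA that silences 1 X chromosome in female cells, reached 2094 CPM in the female and 1.15 CPM in the male library, with a UMI in 88.0% of female and 0.614% of male nuclei (median depth 2694 and 4381 UMIs). Its antisense partner Tsix, which overlaps it on the opposite strand, reached 379 and 3.74 CPM. The Y-linked Eif2s3y had 164 CPM in the male and 0.606 CPM in the female library, Uty 140 and 0.875 CPM, Ddx3y 49.1 and 0.269 CPM, and Kdm5d 45.7 and 0.202 CPM. Of 8 X-linked genes that escape inactivation, 7 were higher in the female library over all nuclei, with a median log2 male to female ratio of -0.34 at the 0.01 percentile of random lists. The histone demethylase Kdm6a stood at -0.51 and the translation factor Eif2s3x at -0.50, 5530601H04Rik at -0.27, and the noncoding RNA Ftx at 0.01. With nuclei thinned to 1000 UMIs, 5530601H04Rik stood at 0.00.

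Under the filters used here, and among the 8 main classes, the libraries differed most in granule neurons of the dentate gyrus, the input field of the hippocampus. They formed 28.8% of male nuclei (interval 28.1% to 29.6%) and 10.3% of female nuclei (9.83% to 10.7%), a ratio of 2.80 (2.65 to 2.97). Subiculum or entorhinal excitatory neurons formed 7.82% and 3.31% (ratio 2.36, interval 2.13 to 2.62), CA3 pyramidal neurons 5.65% and 3.55% (1.59, 1.43 to 1.77), GABAergic interneurons 4.54% and 3.13% (1.45, 1.29 to 1.63), microglia or macrophages 5.65% and 4.06% (1.39, 1.26 to 1.54) and CA1 pyramidal neurons 12.2% and 9.13% (1.34, 1.25 to 1.43). Oligodendrocytes, the myelinating cells, formed 16.7% of male and 20.9% of female nuclei (0.802, 0.761 to 0.845) and astrocytes 8.65% and 9.68% (0.893, 0.828 to 0.962). Within most classes the depths were close, with medians of 5064 and 5604 UMIs in granule neurons and 1653.5 and 1725.5 UMIs in oligodendrocytes, but subiculum neurons had 6770.5 and 9739.5 UMIs.

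The smaller classes included cells of tissue next to the hippocampus. Thalamic or habenular neurons formed 0.865% of female nuclei and 0 of the 14007 male nuclei, which allows up to 0.0214%, while choroid plexus epithelial cells formed 0.178% of male nuclei and 0 of the 17224 female nuclei, which allows up to 0.0174%. Endothelial cells formed 0.186% of male and 0.923% of female nuclei, ependymal cells 0.0357% and 0.464%, pericytes or smooth muscle cells 0.264% and 0.435%, and fibroblasts or meningeal cells 0.236% and 0.453%. Oligodendrocyte precursors formed 2.56% and 2.89%, and Cajal-Retzius cells 0.214% and 0.0987%. Nuclei in unnamed clusters formed 6.28% of the male and 29.9% of the female nuclei and enter every share as part of the total. Over named classes only, the CA1 ratio was 0.999, and with at least 1000 genes and at most 1% mitochondrial UMIs it was 0.751, CA3 0.878, GABAergic interneurons 0.825, granule neurons 1.80 and microglia 3.52. At Leiden resolution 0.5 the GABAergic ratio was 0.508 and the subiculum ratio 1.55, but both classes were made up otherwise there. The GABAergic cluster (832 male and 1789 female nuclei before called doublets were removed) had among its leading genes 6330411D24Rik, which leads unnamed cluster 26 here. The cluster led by Gm49906, Tshz2 and Dpp10, which is part of the subiculum class here, was left unnamed there. Across settings the direction of the CA1, CA3 and GABAergic ratios was not fixed. Nor was the first rank of granule neurons, which microglia took under the stricter filter. That microglia ratio rests on 92 male and 18 female nuclei. Another cluster led by Inpp5d and Ikzf1 (177 and 151 nuclei before called doublets were removed) was left unnamed under that filter.

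**Figure D1:**
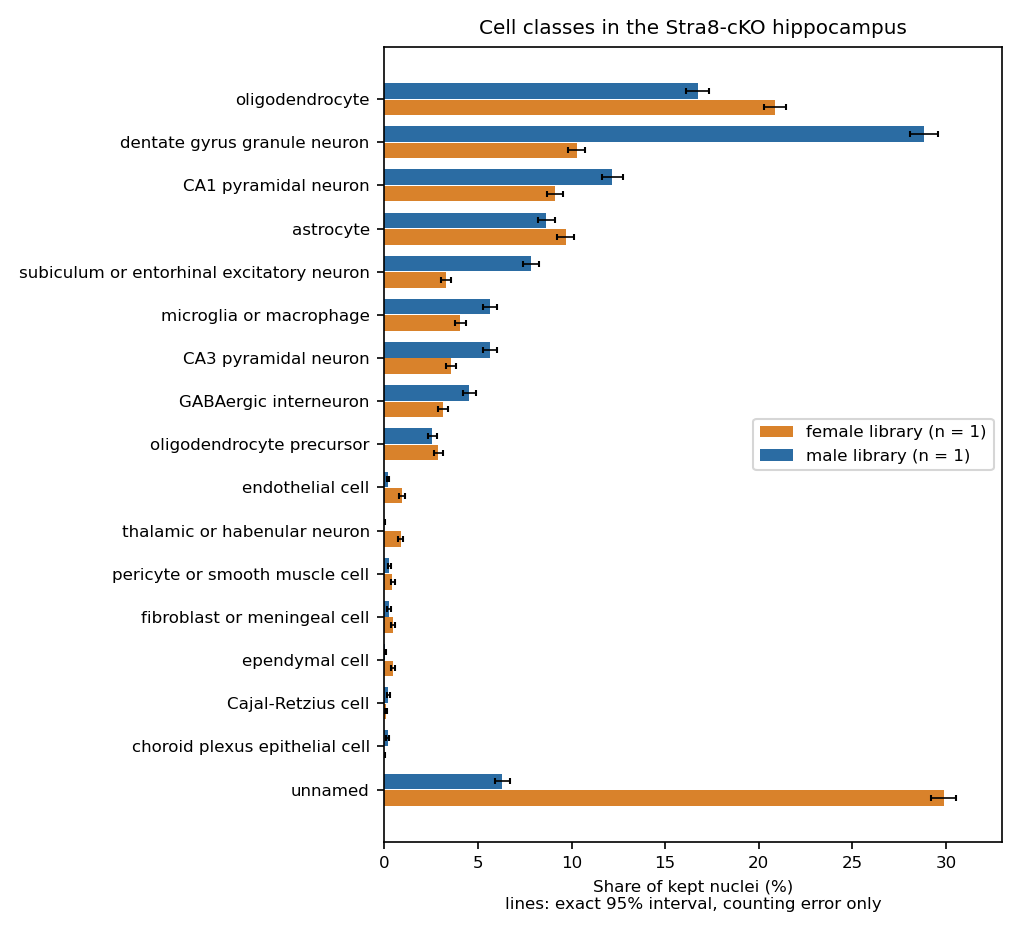
Share of kept nuclei (%) per cell class in the male library (blue, n = 1) and the female library (orange, n = 1), with lines for the exact binomial 95% interval of counting error. Granule neurons form 28.8% of male and 10.3% of female nuclei, and unnamed clusters 6.28% and 29.9%.

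Within several classes the libraries fell into different clusters. Oligodendrocytes split into cluster 11, led by Aspa, Prr5l and Neat1 and holding 95.1% of the male class, and cluster 18, led by A230001M10Rik and Prr5l and holding 95.4% of the female class. Granule neurons of cluster 1, led by Glis3, Stra6 and Arsj, formed 78.1% of the male and 95.3% of the female class, and those of cluster 10, led by C1ql2, C1ql3 and Jun, formed 21.9% and 4.69%. The subiculum class took 43.2% of its male but 8.60% of its female nuclei from cluster 15, which is led by Gm49906, Tshz2, Dpp10 and Npsr1. Astrocytes came from cluster 9 (78.0% and 80.6%), led by Gm6145 and Gli3, and cluster 19, in which 35.4% of nuclei were called doublets before these were removed. GABAergic interneurons came mainly from cluster 17 (51.6% and 47.7%), led by Kcnmb2 and Tll1. CA1 neurons (led by Gm10754 and Galntl6), CA3 neurons (led by Nectin3 and Trhde) and microglia (led by Inpp5d and Ikzf1) each came from 1 cluster.

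The question then was which genes differed between the libraries in many classes at once. Ttr, the thyroid hormone carrier made by the choroid plexus and a marker of that tissue, was higher in the male library in all 8 main classes, by a median log2 ratio of 3.58, or 11.9-fold. Several genes known from neurons were among the 10 with the largest median, which were picked for being higher in the male library in every class that met the rule. The synaptic organiser C1ql3 had a median of 1.06 over 8 classes, the neuronal pentraxin receptor Nptxr 1.10 over 8, the secreted C1qtnf4 1.26 over 8, the inward rectifier channel Kcnj4 1.01 over 4 and the Ras-like Rasl10a 1.00 over 5. C1ql2, a granule neuron marker, had 1.77 over 4 classes, and Cfap54, a marker of ciliated ependymal cells, 1.43 over 6. The transcription factors Cebpb and Jun stood at 1.21 and 1.00, each over 4 classes. As a fraction of all UMIs, some of these genes were as high in glia as in neurons, Nptxr and Kcnj4 being highest in microglia and C1qtnf4 in choroid plexus cells. Nptxr had 397 CPM in male and 187 CPM in female microglia against 257 and 118 CPM in granule neurons, and C1ql2 76.5 and 18.5 CPM in oligodendrocytes against 79.3 and 23.6 CPM in granule neurons, whereas C1ql3 had 183 and 70.6 CPM in oligodendrocytes and 341 and 203 CPM in granule neurons. The vesicle release genes as a list had a median log2 ratio of 0.66 in oligodendrocytes, 0.61 in astrocytes and 0.60 in microglia.

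Genes higher in the female library in many classes were of other kinds. Their largest median was smaller in size than that of Ttr (3.58), but the sizes of the medians overlapped between the female and the male side. The fibrillar collagen gene Col11a1 had a median log2 ratio of -1.24 over 4 classes, with 61.7 CPM in male and 255 CPM in female CA3 neurons. The filamin-binding Filip1 stood at -1.05 over 7 classes, the peptide transporter Slc15a2 between -1.35 in granule neurons and -0.65 in CA3 neurons over 5, the ubiquitin ligase Rnf121 between -1.82 in astrocytes and -0.77 in CA1 neurons over 8, the mitochondrial aspartate-glutamate carrier Slc25a13 at -0.97 over 4, the mTOR complex component Prr5l at -0.81 over 5 and the zinc finger gene Zfp983 at -0.77 over 6. Gm22146 (-1.13 over 4 classes; chromosome 17, 28446500 to 28456457) lies antisense inside Fkbp5, a target of the glucocorticoid receptor. The noncoding RNAs Gm48530 and Gm41804 stood at -0.92 and -0.78, each over 4 classes. Over all genes that met the rule, 2053 had the higher value in the male and 388 in the female library in every class, which is a count of signs in these libraries and not of tested genes. The median gene of a class was itself higher in the male library, by 0.05 in astrocytes to 0.11 in CA3 and subiculum neurons, and by 0.10 in oligodendrocytes, and all ratios are given before this shift is taken off. In CA1 neurons thinned to 1000 UMIs, Rasl10a stood at -0.02 in place of 0.42. In microglia of at least 1000 genes and at most 1% mitochondrial UMIs Kcnj4 stood at -0.87, but that class held only 92 male and 18 female nuclei.

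**Figure D2:**
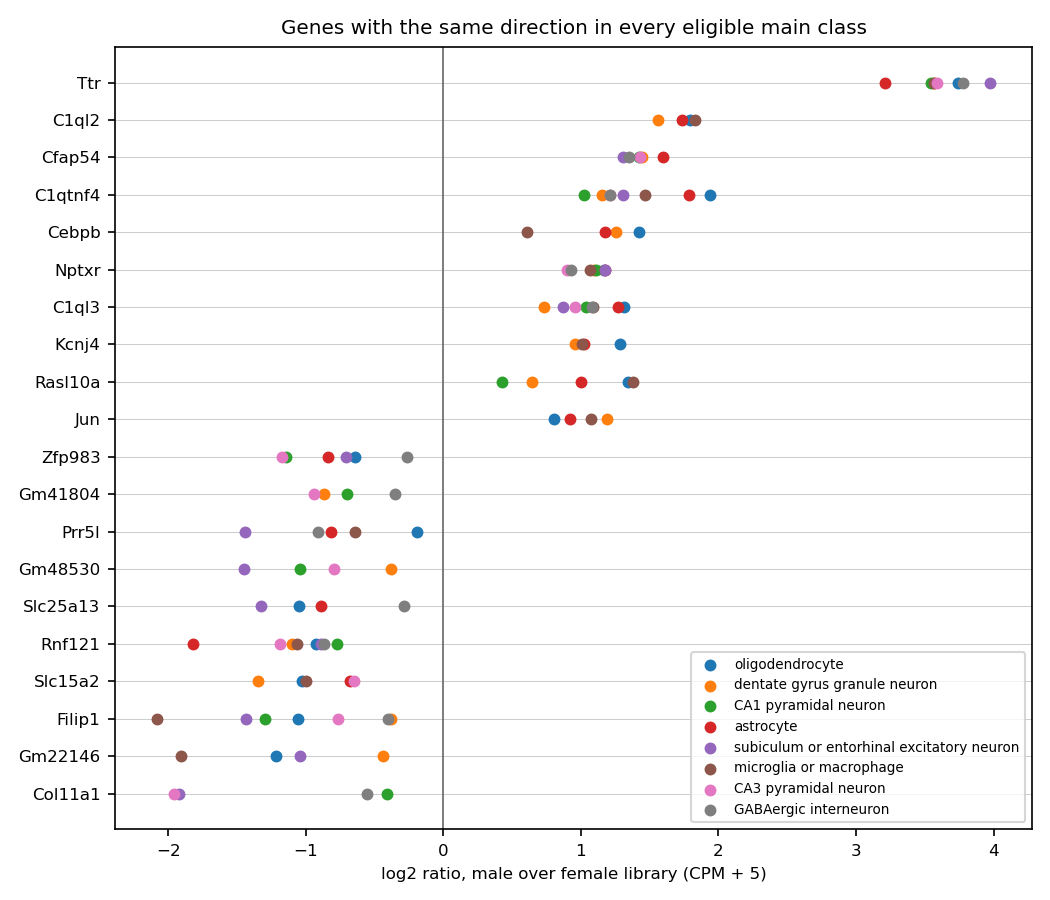
Log2 male to female ratio (CPM plus 5; n = 1 library per sex) of 20 shared genes in each main class that met the rule, with 1 point per class. The median over classes is 3.58 for Ttr, 1.77 for C1ql2 and -1.24 for Col11a1.

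Sex-linked genes aside, oligodendrocytes held the largest log2 ratio of a named gene, taken with 5 CPM added to each side. Zfp804b, a zinc finger gene (ENSMUSG00000092094; chromosome 5, 6769010 to 7344756), had 1134 CPM in male and 18.2 CPM in female oligodendrocytes, a log2 ratio of 5.62 (interval 5.41 to 5.83). At least 1 Zfp804b UMI lay in 55.3% of male and 2.67% of female oligodendrocytes (median depth 1653.5 and 1725.5 UMIs), against 4.93% of male and 2.86% of female microglia (1542 and 1608 UMIs). In granule neurons, which express it in both libraries, it was higher in the female library (464 and 797 CPM, log2 ratio -0.77), and in GABAergic interneurons it had 666 and 725 CPM. Polr3e, a subunit of RNA polymerase III, was higher in female oligodendrocytes, with 125 CPM in the male and 652 CPM in the female library (log2 ratio -2.34, -2.46 to -2.21). Mylk, the myosin light chain kinase, had 5.63 and 63.7 CPM (-2.69), and Npsr1, the receptor of neuropeptide S, 4.93 and 41.4 CPM (-2.22). Within cluster 11 the log2 ratio was 3.73 for Zfp804b, -1.36 for Polr3e, -2.38 for Mylk and -0.93 (-2.05 to 0.24) for Npsr1, and within cluster 18 it was 5.71, -1.59, -2.84 and -1.74 (-2.97 to -0.29). The channel subunit gene Kcng2 (1.46) and the glutamate receptor accessory gene Shisa9 (1.36) were higher in the male library, and both were highest in granule neurons. Under the filter of at least 1000 genes and at most 1% mitochondrial UMIs with classes rebuilt, the Zfp804b ratio was 1.43 and that of Polr3e -1.51. That rebuilt class took in 2 clusters of which 89.0% to 99.5% of nuclei lay in clusters removed here as doublets, and in nuclei of the class used here that passed that filter (353 male and 141 female nuclei) the Zfp804b ratio was 7.28 (6.12 to 8.06), with only 4.45 CPM in the female library. That female level lies below the 5 CPM added to each side, so the direction can be read from this ratio but its size is poorly fixed.

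Genes for myelin were split in oligodendrocytes: of 16 measured, 5 were higher in the male and 11 in the female library, with a median log2 ratio of -0.07 at the 16.8 percentile of random lists. Mobp (-0.67) and Mog (-0.51) were higher in the female library, and the iron carrier Trf and the galactolipid enzyme Ugt8a (both 0.32) in the male library. Of 21 genes of cholesterol and lipid synthesis, 18 were higher in the male library (median 0.24, 94.7 percentile), among them the mevalonate pathway enzymes Mvk (0.66) and Fdps (0.58), while the fatty acid enzyme Acaca stood at -0.58 and Lss at -0.10. Under the stricter filter with rebuilt classes the myelin median was 0.43 and Mog stood at 0.05. With the classes kept, the cholesterol and lipid median was 0.04.

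Target genes of the glucocorticoid receptor were higher in the female library, with the largest ratios in glia. In oligodendrocytes 14 of 16 measured members were higher in the female library, with a median log2 ratio of -0.66 (interval -0.74 to -0.53) at the 0.00 percentile of random lists. The cell cycle inhibitor Cdkn1a stood at -2.01 (1.41 and 20.8 CPM) and the receptor co-chaperone Fkbp5 at -1.66 (72.8 and 242 CPM), while Mertk (0.09) and Per1 (0.13) stood close to 0. The median was -0.79 in astrocytes, -0.58 in microglia, -0.47 in GABAergic interneurons, -0.27 in subiculum neurons, -0.16 in CA1 neurons, -0.05 in CA3 neurons and -0.01 in granule neurons. Fkbp5 had 521 CPM in male and 1822 CPM in female microglia, 47.8 and 134 CPM in astrocytes, 75.6 and 156 CPM in subiculum neurons, 129 and 174 CPM in granule neurons, 78.3 and 102 CPM in CA1 neurons and 91.1 and 94.7 CPM in CA3 neurons. Its log2 ratio was -0.91 within oligodendrocyte cluster 11 and -1.23 within cluster 18. Under the stricter filter with rebuilt classes the oligodendrocyte median was -0.21, and -0.73 with the classes kept.

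**Figure D3:**
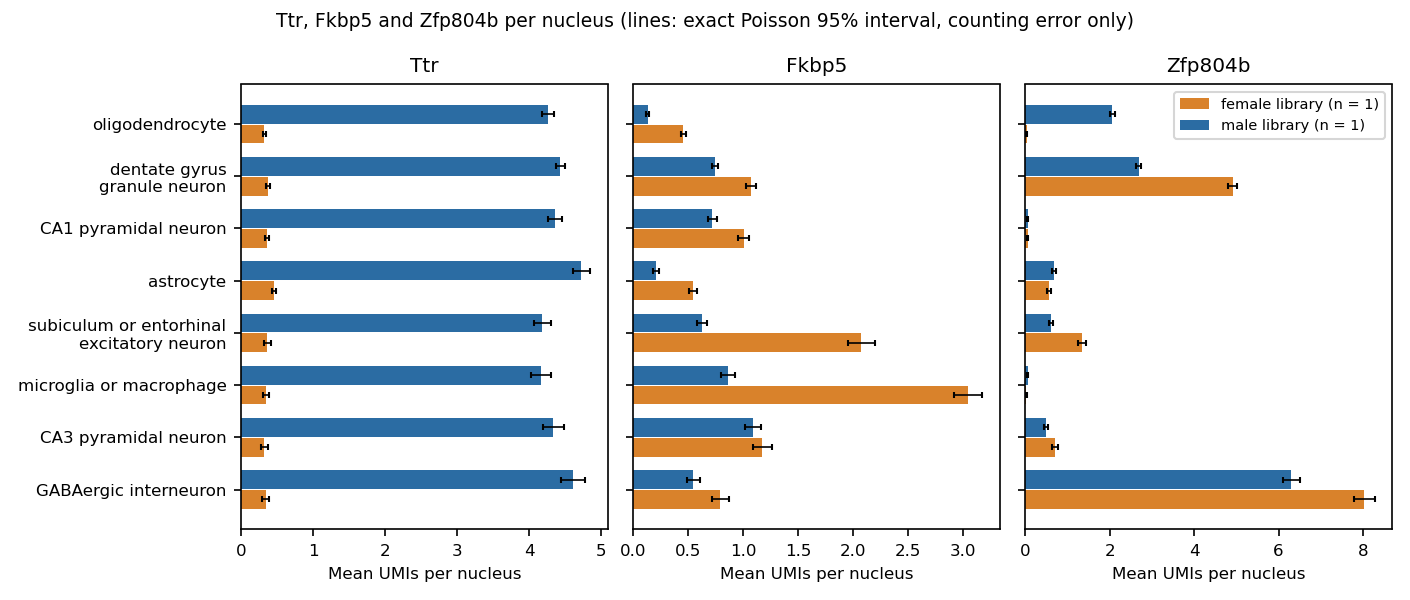
Mean UMIs per nucleus of Ttr, Fkbp5 and Zfp804b in the 8 main classes of the male library (blue, n = 1) and the female library (orange, n = 1), with lines for the exact Poisson 95% interval. Male Ttr lies between 4.16 and 4.73 UMIs in each class, Fkbp5 differs by class, and Zfp804b is at 2.06 UMIs in male and 0.0345 UMIs in female oligodendrocytes.

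In microglia, the immune cells of the brain, the genes with the largest ratios were not those of microglial states. The transcription factor Zbtb16, itself a glucocorticoid target, had 33.6 CPM in the male and 231 CPM in the female library (log2 ratio -2.61), the kinase substrate Cables1 113 and 576 CPM (-2.30) and the F-box gene Fbxl7 15.3 and 128 CPM (-2.72). Zbtb16 and Fbxl7 were highest in fibroblasts or meningeal cells, and Cables1 in microglia. The genes higher in male microglia, the adenylate kinase Ak5 (1.80), the vesicle protein gene Synpr (1.72) and Shisa9 (1.39), have their highest levels in CA3 or granule neurons. Of 14 homeostatic microglia genes, 9 were higher in the male library (median 0.19, 95.8 percentile), with the receptor gene Fcrls at 1.20 and the transcription factor Sall1 at 0.45 against the sugar transporter Slc2a5 at -0.43 and the purine receptor P2ry12 at -0.21. Activated microglia genes were split, 5 of 9 being higher in the male library (median 0.03, 44.9 percentile), from the protease genes Ctsb (0.35) and Ctsd (0.24) to Cd68 (-0.18) and B2m (-0.50), and their mean of -0.01 had the other sign. The interferon genes were also split, 3 of 6 each way (median 0.03, 34.5 percentile), from Parp14 (0.52) and Stat2 (0.23) to Rnf213 (-0.01) and Ifi27 (-0.12). Centred on the median gene, the activated microglia and the interferon median were both -0.04. Without doublet removal Fbxl7 stood at -0.57, Zbtb16 at -1.27 and Synpr at 0.54, and under the stricter filter Fcrls at -0.09, Ctsb at -0.17 and Ctsd at -0.37. The microglia class rebuilt under that filter held only 92 male and 18 female nuclei.

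Astrocytes had lower levels of both astrocyte lists in the male library. Of 16 homeostatic genes, 15 were higher in the female library, with a median log2 ratio of -0.31 (interval -0.41 to -0.27) at the 0.00 percentile. The GABA transporter Slc6a11 stood at -0.93 and the gap junction gene Gjb6 at -0.87, whereas Aldoc stood at 0.01. Of 12 reactive genes, 9 were higher in the female library (median -0.22, 0.36 percentile), among them Vim (-1.09) and Cd44 (-0.64), with the complement gene C4b (0.43) and the protease inhibitor Serpina3n (0.50) higher in the male library. The summed vesicle release genes went the other way in this class, with 4110 CPM in the male and 2728 CPM in the female library. Outside the lists, the noncoding B230323A14Rik had 2 UMIs in male and 264 UMIs in female astrocytes (log2 ratio -3.02, -3.12 to -2.76). The matrix gene Mamdc2 stood at -2.15 and Txnip, which binds thioredoxin, at -1.43. All 3 were highest in ependymal cells (0.464% of female and 0.0357% of male nuclei), but whether these account for the astrocyte ratios was not tested. The lipid transfer gene C2cd2l (1.25), the phosphatase Dusp7 (1.20) and the membrane protein gene Basp1 (1.19) were higher in the male library. Under the stricter filter with rebuilt classes the reactive median was 0.03, and in nuclei thinned to 1000 UMIs Cd44 stood at 0.19.

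In granule neurons most genes for synaptic release, protein folding and respiration were higher in the male library. The ratios pool clusters 1 and 10, and cluster 10 formed 21.9% of the male and 4.69% of the female class. They therefore also carry the unlike mix of clusters, and ratios within each cluster were not taken. Of 20 vesicle release genes, 14 were higher in the male library, with a median log2 ratio of 0.40 (0.33 to 0.44) at the 100 percentile, led by the vesicle proteins Sv2b (0.96) and Sv2a (0.69), against Syn3 (-0.26) and Rims2 (-0.21). Summed over the list, vesicle release UMIs were nearly equal, with 41.5 per nucleus in the male and 42.6 in the female library (log2 ratio of CPM 0.05). All 18 measured heat shock and folding genes were higher in the male library (median 0.37, 100 percentile), from Cryab at 0.02 and Hspe1 at 0.27 to Hsph1 at 0.76 and the constitutive chaperone Hspa8 at 1.34 (283 and 109 CPM). Of 20 nuclear genes of oxidative phosphorylation, 19 were higher in the male library (median 0.35, 99.9 percentile), with Ndufa4 at 0.62 against Sdhb at 0.07 and Sdha at -0.02. The mitochondrially encoded genes went the other way in 8 of 13 members (median -0.10, 2.00 percentile), with mt-Nd3 at -0.62 and mt-Nd6 at -0.44 against mt-Nd4l at 0.14 and mt-Atp8 at 0.23. Of 20 ribosomal protein genes, 16 were higher in the male library (median 0.09, 75.6 percentile), with Rpl3 at 0.52 and Rpl4 at 0.40 against Rps12 at -0.35 and Rps24 at -0.20. In nuclei thinned to 1000 UMIs the median was 0.21 for vesicle release, 0.15 for oxidative phosphorylation and -0.15 for ribosomal protein genes, and mt-Atp8 stood at -0.20. The ribosomal median was -0.12 as a mean over nuclei.

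Of 17 immediate early genes in granule neurons, 13 were higher in the male library (median 0.21, 95.9 percentile), led by Jun (1.19), which also leads cluster 10, and Egr3 (0.59), while Fos (-0.16) and Dusp1 (-0.07) stood lower. Of 19 clock genes, 16 were higher in the male library (median 0.24, 96.7 percentile), with Hlf at 0.59 and Per1 at 0.46 against Bhlhe40 at -0.04 and Rora at -0.12. The cohesin and chromatin genes had a median of 0.10 at the 51.8 percentile, 17 of 24 being higher in the male library, from Dnmt1 (0.40) and Hdac4 (0.34) to Stag1 (-0.14) and Tet2 (-0.40). DNA damage and apoptosis genes were split, 8 of 16 each way (median 0.00, or -0.08 centred on the median gene; 7.53 percentile), from Bax (0.58) and Bbc3 (0.50) to Bcl2l1 (-0.31) and Parp1 (-0.32). Sodium and calcium channel genes had 9 of 19 members higher in the male library (median -0.02, mean 0.10; 15.2 percentile), with the accessory subunit Scn2b at 0.91 against Cacnb2 at -0.19 and Scn3b at -0.26. Potassium channel genes had 9 of 20 higher in the male library (median -0.03, mean 0.04; 7.90 percentile), with Kcnc1 at 0.58 against Kcnq3 at -0.26 and Kcnt2 at -0.40. Single genes outside the lists included the co-chaperone gene Dnajc5b (1.70) and the splicing factor gene Wbp11 (1.52; 105 and 33.3 CPM), both higher in the male library. The heparanase relative Hpse2 (-2.58; 1.41 and 33.5 CPM), the noncoding Gm17167 (-2.22) and the R-spondin receptor Lgr6 (-1.99) were higher in the female library. In nuclei thinned to 1000 UMIs Parp1 and Rora stood at 0.01. These granule neuron ratios, too, carry the unlike share of cluster 10 in the libraries.

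In CA1 neurons, which send the main output of the hippocampus, the receptor lists had medians close to 0, with members on both sides. Of 17 ionotropic glutamate receptor genes, 7 were higher in the male library (median -0.05, mean 0.11; 4.13 percentile), with Grin3a at 0.73 and Gria4 at 0.61 against Grin2a at -0.16 and Grin2d at -0.17. Of 12 GABA-A receptor genes, 4 were higher in the male library (median -0.01, mean 0.04; 16.2 percentile), with Gabrd at 0.47 against Gabra5 at -0.17. The kinase list had 13 of 20 members higher in the male library (median 0.12, 87.8 percentile), with Camk2d at 0.73 against the neurotrophin receptor Ntrk2 at -0.20 and Prkca at -0.38. Dpp10, an accessory subunit of potassium channels, had 89.6 CPM in male and 20.2 CPM in female CA1 neurons (log2 ratio 1.91) but is highest in the subiculum class, where it leads cluster 15. Mctp1, a membrane protein with calcium-binding domains, had 124 and 31.8 CPM (1.81) and was highest in granule neurons (883 CPM), and the noncoding 1700057H15Rik stood at 1.87. The noncoding Gm20629 (-1.13), C630043F03Rik (-1.08) and B230110G15Rik (-0.99) were higher in the female library. At Leiden resolution 2 the Dpp10 ratio was 0.96.

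In CA3 neurons the zinc finger gene Zfp58 (1.46), the noncoding 4930467D21Rik (1.43; 135 and 47.0 CPM) and Serpine3 (1.36) were higher in the male library. Iyd, a deiodinase and a marker of CA3 neurons, was higher in the female library (10.4 and 34.3 CPM, log2 ratio -1.35), as were 4930587E11Rik (-0.98) and Gm13629 (-0.91). In the subiculum class Hpse2 (-2.17), Gm32647 (-1.40) and Gm29865 (-1.34) were higher in the female library. Npsr1 (2.06; 90.5 and 17.8 CPM) leads cluster 15, which held 43.2% of the male and 8.60% of the female class. The collagen gene Col23a1 (1.90) and the phosphatase Cdc14a (1.85) were higher in the male library, but at Leiden resolution 0.5 they stood at 0.57 and -0.29, and over all barcodes at 0.53 and -0.40. Under both of these settings the cluster led by Gm49906, Tshz2 and Dpp10 was left unnamed, so the class held other nuclei.

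GABAergic interneurons had the immediate early genes on the female side. Fosb had 1.33 CPM in the male and 29.1 CPM in the female library (log2 ratio -2.43), Fos 3.65 and 32.2 CPM (-2.10) and Egr1 8.14 and 35.7 CPM (-1.63), and the median of that list was -0.78 at the 0.00 percentile. Of 14 neuropeptide and receptor genes, 9 were higher in the male library (median 0.36, interval 0.20 to 0.49, 99.96 percentile), with Sst at 1.06 (83.9 and 37.7 CPM) and the receptor Npy1r at 0.95 against the receptor Tacr1 at -0.18 and Tac1 at -0.37. Sst, which marks 1 interneuron subtype, also had 85.2 CPM in microglia of both libraries together, a class that should lack it and whose nuclei are shallower (median 1542 and 1608 UMIs, against 8284.5 and 8498 UMIs in interneurons). The phosphatase inhibitor gene Ppp1r14b (1.09) and Yjefn3 (1.05) were higher in the male library. At Leiden resolution 0.5 Fosb stood at -1.49 and Fos at -1.23.

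Over all nuclei, the lists closest to the known role of Stra8 had medians close to 0, with members on both sides. Ratios over all nuclei also carry the unlike make-up of the libraries, in which granule neurons formed 28.8% of male and 10.3% of female nuclei. Unnamed clusters formed 6.28% and 29.9%, so medians and percentiles over all nuclei do not separate expression from cell shares. Of 28 genes of meiotic entry and prophase, 21 were measured, 8 of them higher in the male and 13 in the female library, with a median log2 ratio of -0.08 (-0.10 to -0.02) at the 2.49 percentile. The synaptonemal gene Sycp2 stood at -0.39 and the cohesin gene Smc1b at -0.36, against the RNA helicase Ythdc2 at 0.22 and the transcription factor Zglp1 at 0.23. Of 18 retinoic acid genes, 11 were higher in the male library (median 0.09, 97.7 percentile), with the uptake receptor Stra6 at 0.54 and the synthesis enzyme Rdh10 at 0.47 against the receptor Rarb at -0.73 and the enzyme Aldh1a1 at -1.12. Stra6 leads granule neuron cluster 1, and Aldh1a1 is highest in astrocytes. Sex steroid genes were split 5 to 5 (median 0.02, mean -0.01; 60.5 percentile), from Hsd17b4 and Srd5a1 (both 0.14) to Esr1 (-0.26) and Greb1 (-0.29). Adult neurogenesis genes had 9 of 17 members higher in the male library (median 0.03, 56.5 percentile), with the granule neuron genes Prox1 (0.67) and Neurod2 (0.62) against Gfap (-0.27) and Notch1 (-0.33). Under the stricter filter Gfap stood at 0.19. Of the 28 lists, 11 had a focus median outside the central 95% of random lists.

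**Figure D4:**
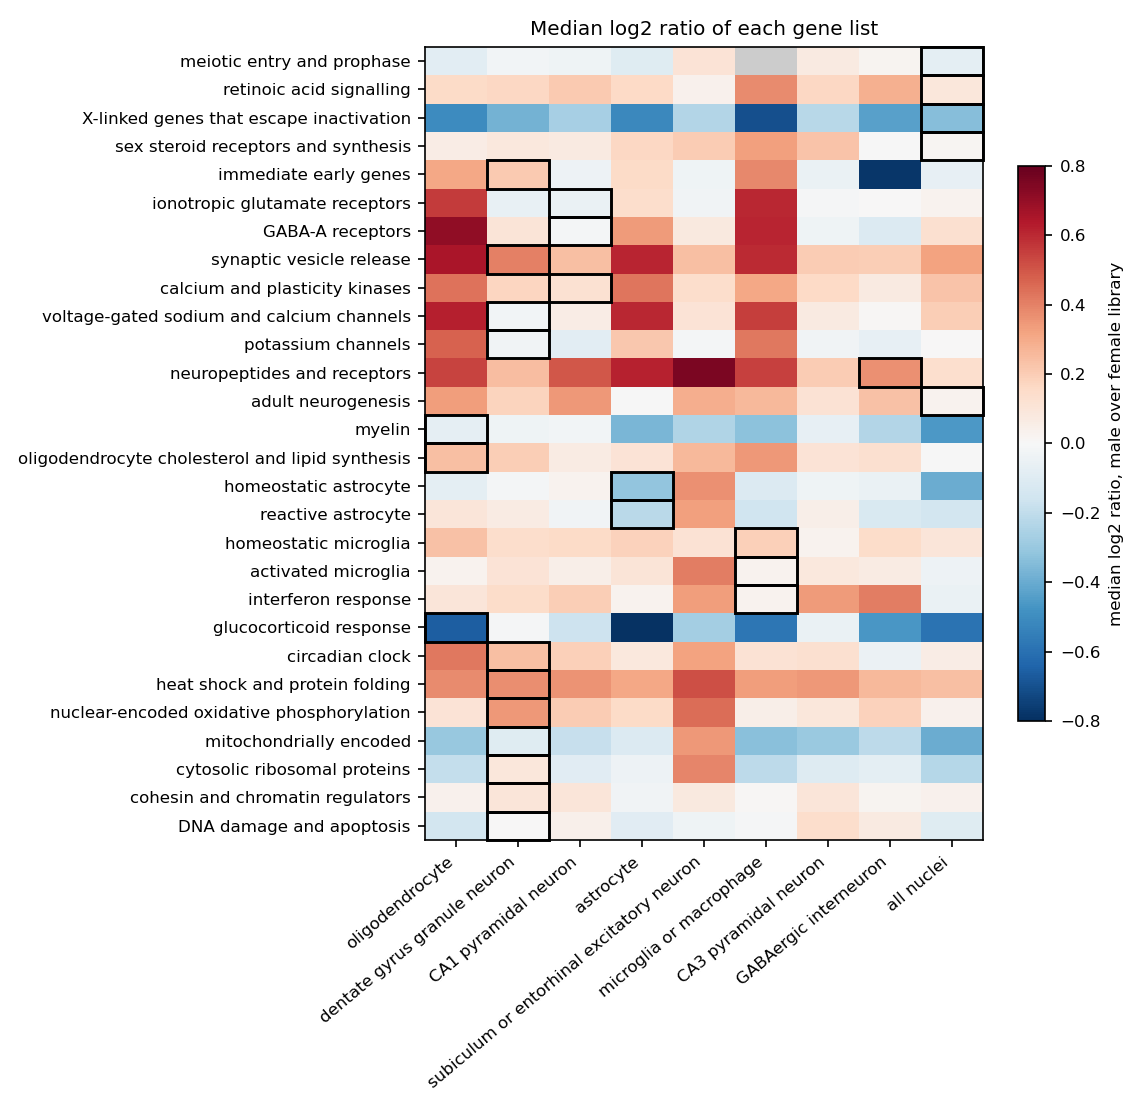
Median log2 male to female ratio of the 28 gene lists (lines) in the 8 main classes and all nuclei (columns), as colour; black boxes mark the focus class and grey a list with too few measured members. Glucocorticoid response reaches -0.79 in astrocytes, and vesicle release 0.66 in oligodendrocytes and 0.40 in granule neurons.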

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

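Nuclei in 5 clusters that the naming rule left without a class were used in no comparison of genes within a class, though they counted in those over all nuclei, and each was present in both libraries above the limit that a count of 0 allows (0.0214% of male and 0.0174% of female nuclei). In cluster 23 fewer than 3 markers of any class passed. The others had a candidate class, but their 20 leading genes held no more of its markers than of another class. The candidates were GABAergic interneurons for cluster 2, CA3 neurons for 22, Cajal-Retzius cells for 26 and immature granule neurons for 30. Cluster 26 had 1 leading marker of its candidate and 1 of another class, and cluster 30 had 0 and 3. Cluster 23 held 0.250% of male and 13.1% of female nuclei, at median depths of 2053 and 1906.5 UMIs, and was led by Ccdc152, Actb, the mitochondrial mt-Nd6 and haemoglobin genes. Cluster 2 held 4.86% and 9.95%, at 1317 and 1044 UMIs, and was led by Actb, the haemoglobin gene Hbb-bs and Ywhah. Cluster 26 held 0.343% and 5.46%, at 8952.5 and 6941 UMIs, and was led by 6330411D24Rik, Pld5 and the transcription factors Ebf1 and Ebf2. Cluster 22 held 0.792% and 1.20%, at 16207 and 16500 UMIs, and was led by Gm32647 and Csf2rb2. Csf2rb2 is on the marker list of hilar mossy neurons, and under the stricter filter a cluster also led by Gm32647 and Csf2rb2 was named hilar mossy neuron. That cluster (68 male and 40 female nuclei before called doublets were removed) had only 1 marker of the class among its 20 leading genes. Its leading genes also included Otx2os1 and Tmem72, which lead the choroid plexus cluster here, so the name is weakly backed. Cluster 30 held 0.0357% and 0.116% and was led by 2610307P16Rik, Gm38505 and Pbx3. The female to male ratio of shares was 52.6 for cluster 23 (37.7 to 75.7), 15.9 for cluster 26 (11.9 to 21.8), 3.25 for cluster 30 (1.18 to 11.1), 2.05 for cluster 2 (1.87 to 2.24) and 1.52 for cluster 22 (1.20 to 1.93). Whether clusters 2 and 23 hold debris or damaged nuclei was not tested, and they count in the total of every share.

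Of the 10 tests below, those of free choroid plexus RNA, free neuronal RNA as an equal number of UMIs, low nuclear quality, depth and a variant of Zfp804b were set up after the result they measure had been seen. The only biological explanation in the design is sex, which stays open as untested, because each sex has 1 library, and the number of animals is not given in the sources used here.

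Ttr and, in glia, vesicle release genes were higher in the male library in classes that should make little of them. Male nuclei held nearly the same number of Ttr UMIs in each of the 8 main classes, the highest mean being 1.14 times the lowest (1.11 to 1.19), which would follow if choroid plexus RNA were free in the male suspension. For free neuronal RNA the values disagree: the male to female ratio of vesicle release UMIs per nucleus was alike in the 3 glial classes (highest 1.05 times the lowest, 1.03 to 1.09), but the male excess was 2.18 UMIs in oligodendrocytes, 2.08 in microglia and 6.83 in astrocytes, a factor of 3.28 (3.03 to 3.68) that an equal number of UMIs per nucleus does not give. In oligodendrocytes undetected doublets are argued against, since the tenth of male nuclei with most vesicle release UMIs held 28.3% of them (27.6% to 29.1%). That share was 27.5% in the female library, and it would be 22.7% in the male library if spread by depth. Doublets were not tested in astrocytes or microglia, and 35.4% of astrocyte cluster 19 were called doublets before these were removed. Ttr may therefore reflect free RNA, while the source of the vesicle release UMIs in glia stays open.

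Glucocorticoid response genes were higher in the female library, with the largest ratios in glia. Free RNA as the whole cause is argued against, since the female excess of Fkbp5 UMIs per nucleus was 24.1 times as large (at least 11.01, with no upper limit) in microglia (2.18) as in CA3 neurons (0.0908), it was 1.45 in subiculum neurons, and that of the summed list was 2.67 in oligodendrocytes and 1.04 in granule neurons. The Fkbp5 excess was alike, however, in oligodendrocytes (0.326), granule neurons (0.327), astrocytes (0.337), CA1 neurons (0.288) and GABAergic interneurons (0.243). As an equal number of UMIs per nucleus, free RNA could account for Fkbp5 in those classes only under a further condition. CA3 neurons, with an excess of 0.0908, would have to hold less Fkbp5 of their own in the female library. That was not tested, so free RNA stays open there. In oligodendrocytes the median depths were close (1653.5 UMIs in the male and 1725.5 UMIs in the female library). The list median was -0.75 in nuclei thinned to 1000 UMIs. Random thinning leaves the expected CPM of a nucleus unchanged, so that test cannot decide on depth. Low quality is argued against in oligodendrocytes by a median of -0.73 (-1.07 to -0.57) in the nuclei of the class with at least 1000 genes and at most 1% mitochondrial UMIs (353 of 2344 male and 141 of 3594 female, 10 of 16 list members). The test of low quality replaced one with classes rebuilt (-0.21, undecided) after both values had been seen, because the rebuilt class took in clusters removed as doublets. A difference in stress or in the hour of sampling was not tested, like sex.

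Zfp804b was higher in male than in female oligodendrocytes. Free RNA is argued against, since male oligodendrocytes held 36.2 times as many Zfp804b UMIs per nucleus as male microglia (28.2 to 51.5), and a variant acting in all cells by a ratio of -0.77 (-0.81 to -0.73) in granule neurons. For another kind of oligodendrocyte in the male dissection, the ratio was 3.73 (3.19 to 4.33) within cluster 11. Cluster 11 held 95.1% of the male and cluster 18 95.4% of the female class, so the clusters nearly follow the libraries. The test within cluster 11 therefore cannot tell a kind of oligodendrocyte from a library. It took the place of one for a few misassigned nuclei, which the 55.3% of male oligodendrocytes with a UMI had argued against, so 4 explanations were tried and the last was chosen after the others. A variant acting only in oligodendrocytes, or another kind of oligodendrocyte in 1 of the dissections, could account for the pattern. Both stay open, like sex.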

How the results depend on the processing

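Of 158 ratios of shared and class genes, list members not counted, 156 to 158 kept their direction under each alternative, and 9 to 11 lists lay outside the central 95% of random lists (11 as reported). Over all alternatives, list medians were the same in 342 of 415 values (68 moved, 5 reversed), ratios of all named genes, list members included, in 2955 of 3471 (496 moved, 20 reversed) and share ratios in 35 of 64 (24 moved, 5 reversed). Only values whose interval left out a ratio of equality could count as reversed, so sign changes of medians near 0 are not among them. For the values below the cause was not tested, except that named classes only takes the unnamed nuclei out of the total. Removing clusters with over 20% called doublets, named classes only, and the stricter filter with classes kept were added after the data had been seen. Under the stricter filter the activated microglia and interferon lists had no value, nor had the interferon list with members of at least 200 UMIs. The median depth of all kept nuclei was lower in the female library, but that of each main class was higher. No paired analysis was possible because each group has 1 library.

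Over all barcodes, the share ratio was 1.66 for subiculum neurons and 1.02 for GABAergic interneurons, and Cdc14a stood at -0.40. With at least 1000 genes and at most 1% mitochondrial UMIs, the nuclei kept in the female library were 6573, and share ratios were 1.80 for granule neurons, 0.751 for CA1, 1.397 for subiculum, 0.878 for CA3 neurons, 0.825 for GABAergic interneurons and 3.52 for microglia. Kcnj4 (microglia) stood at -0.87, Prr5l (oligodendrocytes) at 0.28, Gfap at 0.19, Mog at 0.0529, Fcrls at -0.0939, Ctsd at -0.37 and Ctsb at -0.17, and the medians were 0.43 for myelin and 0.0266 for reactive astrocyte genes. With the classes kept, Kcnj4 stood at -0.90, Notch1 at 0.0184, Gfap at 0.23, Ctsd at -0.34 and mt-Atp8 at -0.00742. Without doublet removal, share ratios were 2.55 for granule neurons, 1.23 for CA1 neurons and 1.25 for microglia. At Leiden resolution 0.5 they were 1.55 for subiculum, 1.28 for CA3 neurons and 0.508 for GABAergic interneurons, with Cdc14a at -0.29, and at resolution 2 they were 0.684 for astrocytes, 2.09 for subiculum neurons and 1.22 for GABAergic interneurons. With values centred within each library before clustering, they were 2.41 for granule, 2.00 for subiculum, 1.35 for CA3 neurons and 1.21 for GABAergic interneurons, and the ribosomal median was -0.0418, against -0.12 as a mean over nuclei. In nuclei thinned to 1000 UMIs, Rasl10a (CA1) stood at -0.0234, 5530601H04Rik at 0.00402, Cd44 at 0.19, Rora at 0.00982, mt-Atp8 at -0.20, Parp1 at 0.0116 and the ribosomal median at -0.15. Over named classes only, share ratios were 0.600 for oligodendrocytes, 2.10 for granule, 0.999 for CA1, 1.77 for subiculum, 1.19 for CA3 neurons, 1.09 for GABAergic interneurons, 0.668 for astrocytes and 1.04 for microglia.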

Other observations

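Some gene groups differed between classes beyond the class they were read in. Heat shock and folding genes were higher in the male library in every main class, with medians from 0.26 in GABAergic interneurons to 0.51 in subiculum neurons. Mitochondrially encoded genes were higher in the female library in 7 of the 8 main classes, by up to -0.34 in microglia, but stood at 0.35 in subiculum neurons. Ribosomal protein genes likewise stood at -0.21 in microglia, -0.19 in oligodendrocytes and 0.39 in subiculum neurons. The immediate early genes had medians of 0.38 in microglia, 0.31 in oligodendrocytes and 0.21 in granule neurons against -0.78 in GABAergic interneurons. X-linked genes that escape inactivation were higher in the female library in all 8 classes, from -0.22 in CA3 neurons to -0.70 in microglia.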
